A study of Mus musculus with 4 samples.

How the data were processed

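Gene expression was measured in whole mouse retina at 2 ages, 20 months (old) and 3 months (young), on 4 Agilent one-colour arrays. Per the labels, all mice were male, total RNA was extracted with Trizol, and cyanine-3 cRNA was made from it. RNA of 3 mice was pooled for each array, which gave 2 pools and 6 mice per age. The p-values therefore measure the spread between pools, not between single mice. All 4 arrays lay on 1 slide and were read in 1 scan, with the old pools in positions 1 and 2 and the young pools in positions 3 and 4, so that position on the slide and age cannot be told apart.

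The deposited spot intensities were made by the authors with Agilent Feature Extraction 9.5.1.1, per the file headers, with background subtraction and detrending within each array and no normalization between arrays. The software replaces the signal of a spot that does not stand out from the background by a surrogate value, so a dim probe has a bound and not a level. A deposited value table of the same arrays holds ratio values: as deposited, each processed intensity had been divided by the median of its array, a step read from the values and not stated in the labels, so the median is 1 on every array. Its values on the log2 scale differ from the processed intensities by 1 constant per array, equal to minus log2 of that array's median (-8.26, -8.19, -8.03 and -7.91 for old 1, old 2, young 1 and young 2), so it holds the same measurements after median centring, on a linear scale. The yes-or-no flags for spots well above background, saturated or non-uniform were also taken from the deposited scanner output, per the file headers.

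Each array held 45018 spots, of which 43379 were not controls. The share of these well above background was 83.4% for old 1, 77.7% for old 2, 75.9% for young 1 and 77.4% for young 2, and the 75th percentile of the processed intensity was 2332, 2302, 2092 and 1934. No spot was saturated. The number of arrays limits the precision of every value given here.

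For the main test, log2 of the processed intensity minus the 75th percentile of its array was used. Control spots were left out. Spots flagged as outliers were also left out, which removed 146 of the 41174 probes that were not controls, and spots of one probe were averaged. A probe was kept where it was well above background on both arrays of at least 1 age (31723 probes), and each gene was represented by its probe with the highest mean over the 4 arrays, which gave 21028 genes. Names came from the array's accession for 22951 probes, its symbol for 6659 and a synonym for 3109, matched to a RefSeq gene table of the GRCm38.p6 assembly. The other 8455 probes kept the name in the array annotation. No genome build is named for the coordinates in that annotation, so none are printed.

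Old and young pools were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are old over young unless a fold lower is given. Where a gene was not well above background on either array of one age, the fold is given as "at least N-fold". It sets the mean of the bright age against that of the dim age. Each dim value is first raised to the lowest signal well above background on its array. The bound is a value of these means and makes no allowance for the spread between pools, so the true fold can be lower. The adjusted p beside such a bound is that of the limma fit to the values before raising, and does not test the bound. Dim values may be surrogates, so their spread may not be a measured one. A total of 29 gene lists were fixed before the data were examined, from textbook knowledge of immune genes, retinal cell types, stress pathways and tissues next to the retina. They were tested with camera from limma at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists. With an exact permutation test, 2 pools against 2 cannot give a p below 0.333.

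The genes named were set by a rule written before the data were examined. It takes the 10 largest changes in each direction among genes past the threshold whose old and young values do not overlap and which have a gene name, and the 4 members of smallest p in each list described. It also takes Xist and 4 Y-linked genes as a check of the labels. Genes named outside the rule are said to be so. The other settings tried were 3 other normalizations of the processed intensities, normexp background correction with an offset of 50 followed by quantile normalization, the deposited value table, no filter and a stricter filter on dim probes, the mean of a gene's probes, 2 other variance models, the pool number as a block, leaving out each pool, other thresholds, and 2 other set tests. A block for slide or scan was not run, because there was 1 of each.

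The gene test was tested on simulated data for this comparison, with 21028 genes at their real means, variances drawn from the fitted prior and 200 changed genes in each of 20 simulations. It recovered 9.9% of genes changed by 0.7 log2, 62.4% of those changed by 1 log2, 88.8% at 1.5 log2 and 98% at 2.5 log2. None had the wrong sign, and 4.61% of the calls were false. The simulated values follow the model that the test assumes, so these rates need not hold for the calls in the data. In simulations 5 of the lists were shifted by 0.5 log2, with noise independent between genes. Camera with the preset correlation found 100% of them, and camera with an estimated correlation found 4%. Correlated genes were not simulated, so these shares do not show that the preset holds for the data. There the estimated correlation was 0.50 for microglia and macrophages, 0.72 for interferon-stimulated genes, 0.29 for MHC class I and 0.91 for lens. Its lowest value over the lists was -0.14. Figures were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.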

Results

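The series asked, as its title states, about low-grade inflammation of the mouse retina with age. Whole-retina RNA from 20-month-old and 3-month-old male mice was compared on 4 arrays, 2 pools of 3 mice per age. Pools of one age correlated at 0.996 (old) and 0.995 (young) over the 21028 genes tested, and pools of different ages at 0.988 to 0.994. These correlations are across genes, which are not independent replicates. The Y-linked genes Ddx3y (log2 change 0.39, adjusted p = 0.269), Eif2s3y (-0.01), Kdm5d (-0.09) and Uty (-0.08) did not pass the test between ages, and no Xist probe was well above background on more than 1 array.

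In old retina, transcripts of the immune genes Lyz2, Icam1 and H2-K1 and of the globin gene Hba-a1 were higher, and those of the activity-induced transcription factors Egr1, Egr4, Fos and Nr4a1 were lower. In all, 174 genes were higher and 44 lower in old retina, 1.04% of those tested, so that 79.8% of the calls were increases. Agtr1a, an angiotensin II receptor, was at least 13.9-fold higher by its brightest probe (adjusted p = 0.00912), while its second probe, well above background on all 4 arrays, had a log2 change of 1.1. The bound makes no allowance for the spread between pools. The 95% limma interval of the brightest probe's fitted log2 change was 3.29 to 4.5. Il13ra2, a decoy receptor for interleukin 13, was at least 11.6-fold higher (adjusted p = 0.00403). Ccl12, a monocyte-attracting chemokine, rose 7.2-fold (log2 change 2.85 ± 0.32 SE, adjusted p = 0.0386), and Icam1, a leukocyte adhesion molecule, rose 4.94-fold (2.30 ± 0.12 SE, adjusted p = 0.00665). Egr1, an activity-induced transcription factor, fell 3.16-fold, from 1.83 ± 0.01 (SD, n = 2 pools) in young to 0.17 ± 0.16 in old retina on the normalised log2 scale (adjusted p = 0.0106).

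The other genes with the largest fitted increases were Fam90a1b (log2 change 3.06, adjusted p = 0.0166), Upk1b, a uroplakin (2.60, adjusted p = 0.0106), and Itgax, which encodes CD11c of myeloid cells (2.48, adjusted p = 0.0223). Itgax was well above background on 1 of 2 young arrays, and the log2 change of its second probe was 0.15. Genes not well above background in young retina have a bound only, so that their rank by size is not known. The adjusted p beside a bound here is of the fitted change and does not test the bound. Bounds applied to Capn11 (at least 2.49-fold, adjusted p = 0.0329), the retinol dehydrogenase Rdh1 (at least 1.88-fold, adjusted p = 0.00403), Sirpb1a (at least 1.6-fold, adjusted p = 0.00403) and Cstdc2 (at least 1.44-fold, adjusted p = 0.00403). Among the largest fitted decreases, bounds applied to the erythroid gene Hemgn (at least 5.36-fold lower, adjusted p = 0.0207), the olfactory receptor gene Olfr1352 (at least 4.62-fold, adjusted p = 0.0099), Wdr63 (at least 3.34-fold, adjusted p = 0.0108), the Wnt inhibitor Wif1 (at least 2.48-fold, adjusted p = 0.0168) and plasminogen, Plg (at least 2.2-fold, adjusted p = 0.037). Tmem26 (log2 change -2.02, adjusted p = 0.0126) and the acute-phase gene Crp (-1.63, adjusted p = 0.0484) were each well above background on 1 of 2 old arrays. Svopl (-1.34, adjusted p = 0.0106) was measured on all 4 arrays. With normexp background correction, whose offset shrinks changes of dim probes by construction, the changes of all these genes but Fam90a1b, Egr1, Egr4 and Icam1 were smaller by over 1.5 times: Upk1b was at 1.19, Ccl12 at 1.65, Svopl at -0.63, Tmem26 at -0.54 and Crp at -0.36. The calls of Capn11, Sirpb1a, Cstdc2, Wif1, Plg and Crp were lost with it.

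**Figure D1:**
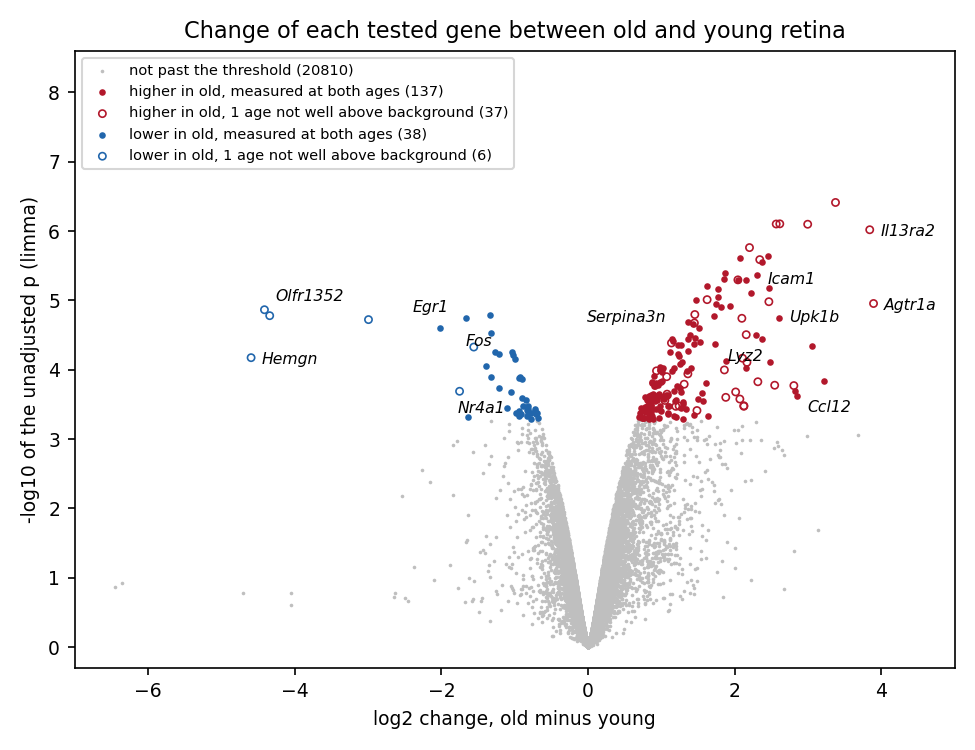
Each point is 1 of 21028 tested genes, with the log2 change (old minus young) on the x axis and -log10 of the unadjusted limma p on the y axis; open circles mark called genes that were not well above background at 1 age, whose plotted change is the fitted value and not a bound. The 174 genes called higher (red) outnumber the 44 called lower (blue).

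By limma with Benjamini-Hochberg adjustment, all 218 called genes had non-overlapping groups, which follows from the call itself with 2 pools per age. So did 49.6% of all tested genes, against 33.3% expected by chance for 2 against 2. Genes are not independent, and position on the slide differs with age, so this excess does not measure an effect of age. Without old 1 there were 91 higher and 10 lower, with 65 of the 218 calls among them, and without old 2 there were 541 and 73, with 176 of the 218. Without young 1 there were 1172 and 483, and without young 2 there were 930 and 289, each with all 218. The calls lost without old 1 include some whose change hardly moved: Fos was at -1.04 with adjusted p = 0.0607, H2-K1 at 1.14 with 0.0551 and Hbb-bt at 1.43 with 0.0656. Also among them were those of Egr4 and Nr4a1, of Alas2, of Tyrobp, Lyz1 and Cd14, and of H2-T23, H2-Q7 and Psmb8, and those of Lyz1, Cd14, Oca2, Vip, Plg and Crp were also lost without old 2. With dim probes kept, limma called 0 of 27603 genes, with 1698 higher and 1007 lower at an unadjusted p under 0.05, against 2018 and 1357 without dim probes.

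Markers of microglia and macrophages were higher in old retina, with a median change of 1.82-fold, and all 26 measured members had a positive change. The lysozyme genes Lyz2 (3.31-fold, adjusted p = 0.0163) and Lyz1 (2.96-fold, adjusted p = 0.0397), the lipopolysaccharide co-receptor gene Cd14 (1.8-fold, adjusted p = 0.0397) and the signalling adaptor gene Tyrobp (2.14-fold, adjusted p = 0.0473) rose. Lyz1 and Lyz2 are close copies, and their probes were not checked for specificity. The other 22 did not pass over all genes, and 25 passed adjusted over the list alone. The list passed camera (adjusted p = 2.87e-20), and its adjusted p = 0.460 with an estimated correlation (camera unadjusted p = 0.0994). Benjamini-Hochberg adjustment gave this same value, the lowest over the lists, to several lists with different unadjusted p. The microglia and macrophage list's mean relative to the 4 arrays was 0.61 in old 1 and 0.29 in old 2, against -0.46 and -0.43 in the young pools. Marker lists of red blood cells (median 2.09-fold) and of pigment epithelium (median 1.51-fold) were also higher in both old pools, beside this list and the other immune and gliosis lists.

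Genes of MHC class I and its peptide loading were higher in both old pools. Of 15 measured members 6 rose and none fell, with a median of 1.78-fold; 13 passed adjusted over the list alone. The heavy chain gene H2-K1 rose 2.34-fold (log2 change 1.23 ± 0.10 SE, adjusted p = 0.0194), H2-T23 1.98-fold (adjusted p = 0.0386), H2-Q7 1.85-fold (adjusted p = 0.0395) and the immunoproteasome gene Psmb8 2.3-fold (adjusted p = 0.0397). The list's camera adjusted p was 3.51e-14, and its adjusted p = 0.460 with an estimated correlation. Some class I heavy chain genes are close copies, and the probes of this list were not checked for specificity. For MHC class II, 1 of 8 members rose, H2-DMb1 (1.91-fold, adjusted p = 0.0397), and the median was 1.14-fold (camera adjusted p = 0.0278, and adjusted p = 0.460 with an estimated correlation). Adjusted over the list alone 2 members were higher and 1 lower, the class II transactivator gene Ciita (log2 change -0.55, adjusted p = 0.164 over all genes). This call was lost in 6 of 14 other settings, with adjusted p up to 0.10; without old 2 it was 0.0944 (median log2 change 0.12, against 0.19) and without young 1 it was 0.0803.

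Interferon-stimulated genes had a median change of 1.86-fold, and 35 of 37 members had a positive change, but none passed over all genes. Adjusted over the list alone 30 were higher, and the list passed camera (adjusted p = 6.82e-19, and adjusted p = 0.460 with an estimated correlation). The antiviral genes Oas2 (log2 change 2.04 ± 0.29 SE, adjusted p = 0.0563), Rsad2 (1.49 ± 0.21, adjusted p = 0.0563) and Usp18 (1.48 ± 0.23, adjusted p = 0.0626) and the membrane protein gene Ifitm3 (0.81 ± 0.14, adjusted p = 0.0735) came nearest. The list mean was 0.72 in old 1 and 0.18 in old 2, with -0.40 and -0.50 in the young pools. Complement genes had a median of 1.51-fold, with 16 of 20 positive and none past the threshold over all genes. Factor B, Cfb (2.28 ± 0.30 SE, adjusted p = 0.0518), the C1 inhibitor gene Serping1 (0.78 ± 0.12, adjusted p = 0.0637), C4b (2.02 ± 0.31, adjusted p = 0.0637) and the integrin gene Itgb2 (0.83 ± 0.12, adjusted p = 0.0584) had the smallest p. Adjusted over the list alone 13 complement genes were higher and 1 lower (camera adjusted p = 2.87e-07, and adjusted p = 0.460 with an estimated correlation).

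In the reactive gliosis list, 4 of 20 members rose and none fell, with a median of 1.44-fold and 11 higher adjusted over the list alone (camera adjusted p = 3.44e-06, and adjusted p = 0.460 with an estimated correlation). They were the protease inhibitors Serpina3n (2.75-fold, adjusted p = 0.0154) and A2m (2.83-fold, adjusted p = 0.0395), lipocalin 2, Lcn2 (1.83-fold, adjusted p = 0.0318), and Bcl3, a regulator of NF-kB (2.53-fold, adjusted p = 0.0441). Gfap, the intermediate filament gene used as the classical gliosis marker and named here after its value was seen, had a log2 change of -0.06 ± 0.30 SE (adjusted p = 0.940). Of 24 cytokine, Toll-like receptor and NF-kB genes, Icam1 rose and 6 were higher adjusted over the list alone, with a median of 1.19-fold (camera adjusted p = 2.3e-06, and adjusted p = 0.460 with an estimated correlation). Tlr4 (log2 change 0.99, adjusted p = 0.0625), Tlr2 (1.32, adjusted p = 0.106) and Tnfrsf1a (0.50, adjusted p = 0.0943) did not pass. Of 19 chemokines and receptors, Ccl12 rose and 5 were higher adjusted over the list alone, with a median of 1.5-fold (camera adjusted p = 0.00328, and adjusted p = 0.556 with an estimated correlation). Ccl2 (2.41 ± 0.45 SE, adjusted p = 0.0939), Ccl3 (at least 2.63-fold, adjusted p = 0.0861) and Ccl6 (0.68, adjusted p = 0.121) did not pass. The chemokine list's median log2 change was 0.58, and 0.26 without old 1 and 0.20 with normexp background correction. With normexp the medians of the gliosis list (0.53) and the cytokine list (0.25) were 0.31 and 0.16.

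**Figure D2:**
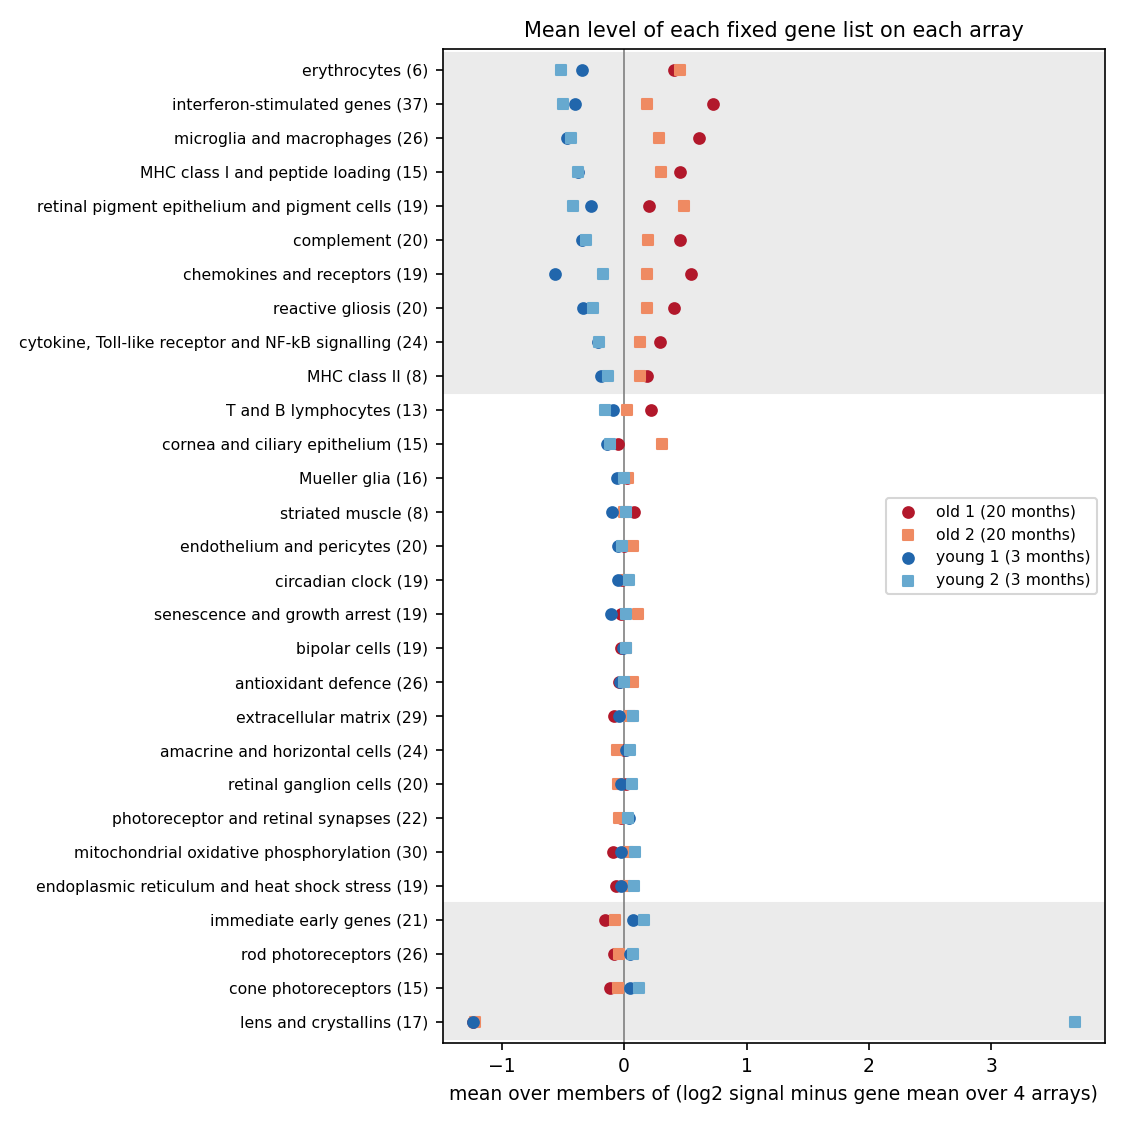
Each row is a fixed gene list with its number of tested members, and each symbol is the mean over members of the normalised log2 signal minus the gene's mean over the 4 arrays, on 1 array; grey bands mark lists past the camera threshold. Both old pools lie above both young pools in the 10 lists called higher, and in the lens list young 2 stands at 3.68 while the other 3 arrays lie near -1.23.

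Both photoreceptor lists had a slightly negative median change and passed camera at its preset correlation only. The rod list had a median log2 change of -0.15, with 21 of 26 members negative (camera adjusted p = 0.00365, and adjusted p = 0.460 with an estimated correlation), and the cone list a median of -0.20, with 12 of 15 negative (camera adjusted p = 0.0101, and adjusted p = 0.556 with an estimated correlation). No member of either list passed, over all genes or adjusted over the list alone. The smallest p in the rod list belonged to the guanylate cyclase gene Gucy2e (-0.50 ± 0.12 SE, adjusted p = 0.148), Esrrb (-0.35), Pde6b (-0.25) and Gnb1 (-0.21). In the cone list they belonged to cone arrestin, Arr3 (-0.48 ± 0.10 SE, adjusted p = 0.113), Gulo (-0.42), the cone opsin gene Opn1mw (-0.40 ± 0.11, adjusted p = 0.190) and Gngt2 (-0.40). The rod call was lost in 4 of 14 other settings: with a smaller median under quantile normalization (-0.07, adjusted p = 0.293), cyclic loess (-0.08, adjusted p = 0.125) and normexp (-0.06, adjusted p = 0.324), and with a median of -0.15 without young 1 (adjusted p = 0.0672). The cone call was lost in 1 of them, without young 2 (median -0.10, adjusted p = 0.0823, the highest over its settings). The log2 change of the second probe of Gucy2e was 0.24.

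Immediate early genes, which neurons switch on with activity or stress, held 4 of the 44 decreases. Besides Egr1, Egr4 fell 2.63-fold (log2 change -1.40 ± 0.13 SE, adjusted p = 0.0248), Fos fell 2.06-fold (-1.04 ± 0.09, adjusted p = 0.0189) and Nr4a1 fell 1.76-fold (-0.82 ± 0.10, adjusted p = 0.0441), and all 4 were lower in both old pools. The other 17 members did not pass. Over the whole list of 21 the median was -0.11 (camera adjusted p = 0.0364, and adjusted p = 0.556 with an estimated correlation), with 4 lower and 2 higher adjusted over the list alone. The list's camera call was lost in 5 of 14 other settings. Among them were median centring and the deposited value table, which is the same centring (median -0.16, camera adjusted p = 0.0578 in both). Others were no filter on dim probes (median -0.11, camera adjusted p = 0.134) and leaving out old 1 (median -0.04). The median thus did not shrink in each setting that lost the call.

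Some marker lists of tissues other than retina differed between pools, and the source of their transcripts was not measured. Red blood cell genes were higher in both old pools: of 6 members 3 rose, the globin genes Hba-a1 (2.57-fold, adjusted p = 0.0154) and Hbb-bt (2.55-fold, adjusted p = 0.0254) and the heme synthesis gene Alas2 (2.25-fold, adjusted p = 0.037), and Slc4a1 did not pass (0.96, adjusted p = 0.123). Of the 6 members 1 had a negative change, and the erythroid gene Hemgn, which is not in the list, fell (at least 5.36-fold lower). The list's median was 2.09-fold, or 1.06 on the log2 scale and 0.68 with normexp (5 higher adjusted over the list alone, camera adjusted p = 8.99e-05, and adjusted p = 0.460 with an estimated correlation). In the list of retinal pigment epithelium and pigment cells, 1 of 19 members rose, the melanosome gene Oca2 (1.8-fold, adjusted p = 0.0386), with a median of 1.51-fold and 9 higher adjusted over the list alone (camera adjusted p = 2.33e-05, and adjusted p = 0.460 with an estimated correlation). Rgr (log2 change 2.09 ± 0.35 SE, adjusted p = 0.0724), Slc16a8 (1.13, adjusted p = 0.0823) and Mitf (0.74, adjusted p = 0.0931) did not pass. This list's median log2 change was 0.60, and 0.90 without old 1, 0.26 without old 2, 0.29 without young 2 and 0.40 with normexp. All 17 lens and crystallin genes had a negative change, with a median of -1.78 (camera adjusted p = 9.07e-04, and adjusted p = 0.726 with an estimated correlation), but none passed over all genes or adjusted over the list alone, and the difference lay in young 2. Cryba1, well above background on 1 of 2 old arrays, stood at 4.86 in young 2 and at -5.96, -6.12 and -7.68 in young 1, old 1 and old 2; Bfsp1 at -1.01 against -4.49, -4.94 and -4.77; the log2 changes of Crygc and Crygd were -0.69 and -0.54. Without young 2 the lens list's median was -0.01 (adjusted p = 0.941, the highest over its 14 other settings), and without young 1 the median was -3.65.

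**Figure D3:**
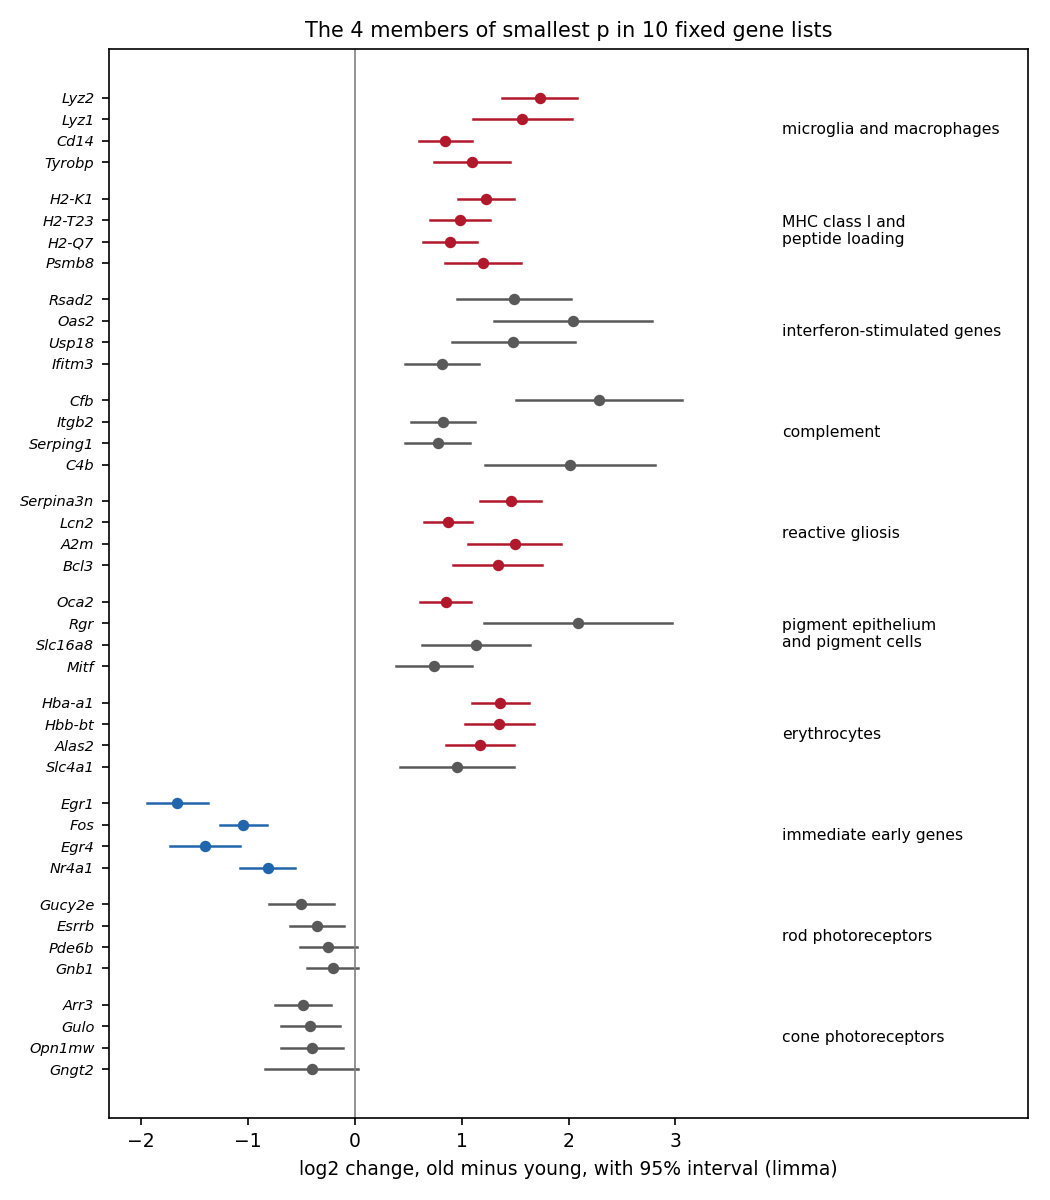
Points are log2 changes (old minus young) with 95% limma intervals for the 4 members of smallest p in 10 fixed lists; red marks genes called higher, blue genes called lower and grey genes not past the threshold. All 4 immediate early genes shown lie below 0, from -1.66 for Egr1 to -0.82 for Nr4a1.

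The other 15 lists did not pass camera, with medians between -0.11 and 0.13 on the log2 scale and adjusted p from 0.108 to 0.904. They were Mueller glia, bipolar cells, amacrine and horizontal cells, retinal ganglion cells, photoreceptor and retinal synapses, endothelium and pericytes, T and B lymphocytes, cornea and ciliary epithelium, striated muscle, antioxidant defence, mitochondrial oxidative phosphorylation, circadian clock, senescence and growth arrest, endoplasmic reticulum and heat shock stress, and extracellular matrix. Single members passed in 4 of them. Vip, a neuropeptide of amacrine cells, fell 1.64-fold (adjusted p = 0.0473), the endothelial clotting factor gene Vwf rose 1.97-fold (adjusted p = 0.0248), Col1a1 rose 1.88-fold (adjusted p = 0.0398), and Upk1b is given above. Other settings brought 4 of the 15 past the threshold, 1 setting each: T and B lymphocytes with the mean of probes (median 0.25, adjusted p = 0.0145), cornea and ciliary epithelium without old 1 (0.29, adjusted p = 0.00447), senescence without old 1 (0.08, adjusted p = 0.0298) and oxidative phosphorylation without old 2 (-0.12, adjusted p = 0.00954). Their medians as tested were 0.13, 0.11, 0.02 and -0.07. For bipolar cells the median (0.01) was positive and the mean and the test were negative. The smallest p in the other lists of retinal cells belonged to Aqp4 in Mueller glia (0.51, adjusted p = 0.102), Grm6 in bipolar cells (-0.28, adjusted p = 0.242), Nefh in ganglion cells (-0.21, adjusted p = 0.379) and Cacna2d4 among synaptic genes (-0.37, adjusted p = 0.176).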

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

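All alternatives here were planned, and the cause of each change was not tested unless the setting itself gives it. The 174 higher and 44 lower genes became 78 and 19 with quantile normalization, 111 and 19 with cyclic loess, 251 and 73 with median centring and with the deposited value table (the same centring), 250 and 76 with normexp, 0 and 0 with no filter on dim probes (limma, 1698 and 1007 at an unadjusted p under 0.05), 272 and 73 with probes well above background on all 4 arrays, 125 and 24 with the mean of probes, 466 and 123 with an intensity trend and 315 and 88 with robust eBayes. An unadjusted p under 0.05 with a change of 2-fold gave 336 and 58. Leaving out 1 pool gave 91 (old 1) to 1172 (young 1) higher and 10 (old 1) to 483 (young 1) lower genes, with 541 and 73 without old 2 and 930 and 289 without young 2, with the lone pool assumed to vary like the others, and 9 to 12 lists higher and 2 to 5 lower. No label says that pool numbers pair the pools. Deviations of same-numbered pools correlated at 0.107, over only 2 pairs, which cannot decide whether they are paired. With the number as a replicate block limma called 0 genes higher and 0 lower (2693 and 2133 at an unadjusted p under 0.05). That fit has fewer residual degrees of freedom. The 10 higher and 4 lower lists became 0 and 0 with an estimated correlation (1 list with an unadjusted p under 0.05) and 0 and 0 with fry (12 lists with an unadjusted p under 0.05), which tests a list alone and not against other genes. The lists of microglia, interferon-stimulated, MHC class I, complement, cytokine, gliosis, chemokine, pigment epithelium and erythrocyte genes passed camera at its preset correlation in all 14 other settings, although the medians of the last 5 moved by over 1.5 times in some. The MHC class II list passed in 8, rods in 10, cones and lens in 13 each and immediate early genes in 9. Median centring and the deposited value table count separately among the 14 settings although they hold the same values. Robust eBayes gives no list test, and a block for slide or scan was not run because all arrays share 1 slide and 1 scan.

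Directions turned only in results that had not passed. For every list the direction is that of camera, and the values given are medians, whose sign need not turn with it. Some medians of lists not past the threshold also changed sign where camera did not turn, and these are not all given. For example, the antioxidant median was 0.00076 as tested and -0.049 with median centring. The bipolar list's test turned with quantile normalization (median 0.034), cyclic loess (0.041), normexp (-0.0029), no filter (0.0071) and mean of probes (0.015). The circadian list turned with median centring and the deposited table (-0.013 in both), mean of probes (-0.0092) and without old 2 or young 1 (leaving out 1 pool gave -0.026 to 0.0043). Striated muscle turned with normexp (0.050) and the stricter filter (-0.19), extracellular matrix with no filter (-0.065) and without old 1 (-0.18 to 0.011 over the pools), and antioxidant defence without old 2 (-0.053 to 0.050). Eif2s3y turned with quantile normalization (0.018), cyclic loess (0.030), normexp (0.012) and without old 2 or young 1 (-0.13 to 0.11 over the pools), and Uty with mean of probes (0.033) and without old 2 (-0.16 to 0.0029). With mean of probes Ebf1 (-0.0016) and Vcan (1.17) also turned. Signal over background limits 35 of the higher and 6 of the lower calls to a bound, and leaves 2 more of the higher calls (Ear10 and a transcript without a gene name, singled out after their values were seen) without even a bound, since their mean old signal does not exceed the mean of the lowest signals well above background on the young arrays.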

Other observations

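The tests of blood, pigment epithelium, lens tissue and age below, the added marker lists, and the test of neighbours without shared name stems were chosen only after the results were seen; the tests of brightness, other splits and neighbouring genes as a whole were set before. The following genes passed the threshold outside the fixed lists and are named after their values were seen. No list of genes like these was tested. Genes expressed in myeloid cells were Nod2 (log2 change 2.23, adjusted p = 0.00816), Ly75 (2.29, adjusted p = 0.0146), Pirb (1.74, adjusted p = 0.00912) and Ms4a7 (1.30, adjusted p = 0.0494). The acute-phase genes Lrg1 (2.05, adjusted p = 0.00665) and Hp (1.45, adjusted p = 0.0473) were also higher, while Crp, another acute-phase gene, was lower (-1.63, adjusted p = 0.0484). Also higher was S100a8, which neutrophils express at high levels (at least 3.68-fold, adjusted p = 0.0393). An added neutrophil list had 7 of 17 genes measured, with a median of 0.62 and an interval over genes of -0.14 to 1.88. The epithelial genes Krt8 (1.29, adjusted p = 0.043) and Gjb2 (2.37, adjusted p = 0.0154) were higher, and Prdm1 (-1.32, adjusted p = 0.0144) and the GABA receptor gene Gabra5 (-1.32, adjusted p = 0.0289) were lower. A second probe of Gabra5 (0.06) had a change of the other sign.

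Of 183 called genes placed on the RefSeq gene order, 16.9% had another called gene among the 2 next tested genes on either side, against a median of 4.37% and a 95th percentile of 8.2% in 10000 random sets (permutation p = 1e-04, the smallest these sets can give). Without MHC genes the share was 12.3% against a median of 3.51% (permutation p = 0.0012). Neighbours that share the letters of their name before the first digit were then also not counted. The share was 6.43% against a median of 3.51% and a 95th percentile of 7.6% (permutation p = 0.126). The excess was thus smaller without MHC genes and neighbours with related names, and whether one remains beyond them is not decided. Close copies such as Lyz1 and Lyz2, Rdh1 and Rdh9, Ssxb1 and Ssxb2, and Ms4a6b and Ms4a6c are among the pairs, and their probes may not separate them. Pairs that are not close copies include Prok1 and Cym, Chia1 and Dennd2d, and Oca2 and Gabra5, the last with opposite directions. Regrouping the 4 arrays gave 0 calls by limma in both other splits (520 and 196 genes at an unadjusted p under 0.05) against 218 (3375), and 1 of the 3 splits, the real one, reached that number; so few splits cannot give a share under 0.05.

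The higher microglia and macrophage list was weighed against brightness, blood and pigment epithelium. Intervals and SE values in this paragraph are over the genes of a list, not between pools. Genes of a list are not independent replicates. Cyclic loess, which removes brightness-dependent differences, left the list's median at 0.85 (interval 0.72 to 1.03), which argues against such a difference as the whole cause. Genes of resident microglia, which blood cells should lack (10 measured, 4 of them also in the microglia and macrophage list), had a median of 0.47 (interval 0.09 to 0.82), which lies above 0 but spans the bound of 0.2 set for the test, so blood left in the vessels stays open, with Hba-a1 2.57-fold higher in old retina. For carried-over pigment epithelium, the microglia mean was lower in old 2 than in old 1 (-0.32), while the fixed pigment list went the other way (0.29 ± 0.31 SE) and the added pigment epithelium genes went the same way (-0.44 ± 0.12 SE); between the young pools the microglia mean differed by 0.029 ± 0.046 SE and the added genes by 0.20 ± 0.11 SE, so neither version decides. Age, the difference the design names, stays open and untested beside these.

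The lower lens list may reflect lens tissue in the pool young 2. Its mean there lay 4.90 log2 above the highest other array, and young 1 differed from the mean of the old pools by -0.0066, which argues against age. Cryaa, named after its values were seen, stood at 6.55 in young 2 and at -5.14, -5.07 and -6.43 in young 1, old 1 and old 2. The retina itself expresses some crystallins, and the amount of lens tissue was not measured.

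The higher pigment epithelium list was tested for unequal amounts of attached pigment epithelium, which would move its genes together between pools of one age. SE values in this paragraph are again over genes, for 1 array against 1 array. Of 18 members of the fixed list differing by over 0.1 log2 between the old pools, 10 were higher in old 1 and 8 in old 2 (55.6% in one direction), but pools with similar extra tissue would also split evenly and the list mean did not differ between them beyond its error (0.29 ± 0.31 SE), so this excludes nothing. That list mixes genes of the pigment epithelium with melanosome genes, so a list of 19 measured pigment epithelium genes was then drawn up with several of their values already seen, 8 of them shared with the fixed list and Otx2, for example, also expressed in the retina; 77.8% of 18 went one way, short of the 80% set for the first test. A minimum of 0.3 log2, tried on the added list before the first minimum was put back, gave 9 of 9 genes, and is not counted as evidence because list and minimum were picked after the values were seen. The amount of attached pigment epithelium therefore cannot be told apart from age for either list (median change of the added genes 0.88, with Rgr at 0.96 and 0.10 in the old and -1.88 and -1.24 in the young pools), and an added melanocyte list (13 genes measured, median 0.20) was higher in old 2 than in old 1 by 0.90 ± 0.35 SE.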
